A study of Humulus lupulus with 6 samples.

How the data were processed

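RNA-seq was done on leaf, apical meristem and stem of Cascade, a cultivar of hop (Humulus lupulus). The plants stood in a glasshouse and received no treatment other than sprays against insects and fungi, per the labels' protocols. The labels list 6 samples, 2 for each of 3 tissues. The same protocols speak of 1 TruSeq RNA library per tissue, each sequenced on a lane of its own, so the 2 samples of a tissue may not be separate plants. The tables analysed here hold 1 count column per tissue, and the column names do not say whether that column holds 1 sample or both. Each column was therefore used as the authors' value for its tissue, with no replicate error.

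Per the file headers, the authors counted fragments per gene with featureCounts 1.6.3, which was run on paired reads with strand setting 1 (forward strand) and otherwise default options. The deposited values are raw counts, that is whole numbers of fragments that were not normalised. HISAT2 2.1.0, an aligner, and StringTie 1.3.3b, a transcript assembler, are named in the submitters' processing notes. Per the file headers, each table was counted against a gene model file of that tissue alone, and the paths speak of a masked and deduplicated Cascade assembly. The genome build has no other name in the sources used here. Whether the kit marked the strand is not given in the sources used here. With a kit that does not mark it, strand-specific counting would leave out the fragments of the other orientation.

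This processing shapes the measurements in several ways. Gene numbers of one table do not correspond to those of another, so tissues were matched by position. A gene without a model in a tissue has no count there, which is not the same as a count of 0. A model that is shorter in the tissue with fewer reads collects fewer fragments from the same RNA. With default options, featureCounts leaves out reads that align to several places, so near-identical gene copies are under-counted by an unknown amount.

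Gene models of the 3 tables were joined into loci wherever they shared at least 1 exonic base on the same strand, and counts were summed per locus and tissue. CPM values, that is counts scaled to a common library total, were computed from the total of each table and scaled further by TMM factors from edgeR 4.0.16 in R 4.3.3, which was used for normalisation only. The factors were 0.759 for leaf, 1.17 for meristem and 1.13 for stem. They were estimated on 33671 of 33811 loci with a model in all tissues that passed edgeR's low-count filter. Locus building and comparisons were run in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

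The intended test, edgeR's quasi-likelihood test over 6 libraries, needs replicates and was not run on these columns. The rule of size fixed for that case before the data were examined was applied instead. A locus was compared where both tissues had a model and the higher tissue reached 10 normalised CPM, and it was called where the fold was at least 4. The rule as fixed did not mention missing models. The need for a model in both tissues was added to it, so loci without a model in the other tissue were not called. The same limits were used for tissue-enriched loci, whose planned definition also needed the test. Such a locus had a model in all tissues and met both limits against each of the other tissues. A count of 0 was raised to 3 counts for the fold, which then is a bound. No p-value was computed across loci. Intervals for folds and shares are exact binomial (Clopper-Pearson) 95% intervals. Those over fragments cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Those over loci or adjacent pairs treat these as independent draws, which neighbouring loci need not be. Neither kind says anything about variation between plants. A count of 0 allows a level of up to 3 counts, which is 0.0184 unscaled CPM in leaf, 0.0221 in meristem and 0.0239 in stem. Counts of 1 to 3 were used as they stand, and their ratios are given with the counting interval.

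The files do not pair their gene numbers with gene names. Of the gene numbers, 0 matched the RefSeq gene table at hand, which describes another assembly (drHumLupu1.1). The gene lists fixed beforehand (photosynthesis, cell cycle, lignin, bitter acids and others) are therefore not scored here. The naming rule for unnamed genes was kept: the 2 loci with the largest fold in each direction of each comparison. The most abundant locus of each tissue was added after the values were seen.

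The procedure was tested on simulated counts before use, in a leaf versus stem comparison of 33811 loci with Poisson noise. Of 100 loci raised 8-fold in leaf, 100% were called, of 100 raised 2-fold 0% were called, and 0 unchanged loci were called. This covers counting noise only. Alternatives were other scaling factors, no filter, scaling within each pair, a CPM minimum of 1 and loci with 1 model per tissue with a length offset. Added after seeing the data were a fold of 2, no scaling factors, merging by span, counts per base of model and 3 restrictions to subsets of loci.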

Results

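The transcriptomes of leaf, apical meristem and growing stem of the hop cultivar Cascade were compared to describe which genes each vegetative tissue uses. The apical meristem is the dividing tip of the shoot from which leaves and stem arise. The labels give 2 samples per tissue, and the counts analysed here come as 1 column per tissue. The counted fragments numbered 162799212 in leaf, 135877224 in meristem and 125454712 in stem. These depths make counting error small for all but the rarest transcripts, and error between plants could not be estimated.

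Leaf had the fewest assembled gene models. Its table listed 51502, against 59990 in meristem and 57985 in stem. Multi-exon models were similar in number, at 29981 in leaf, 30697 in meristem and 30489 in stem. Single-exon models numbered 21521 in leaf, 29293 in meristem and 27496 in stem. The single-exon models took 12.7% of the counted fragments in leaf, 10.2% in meristem and 9.29% in stem. Models with a count of 0 numbered 187, 287 and 212 in the same order.

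**Figure D1:**
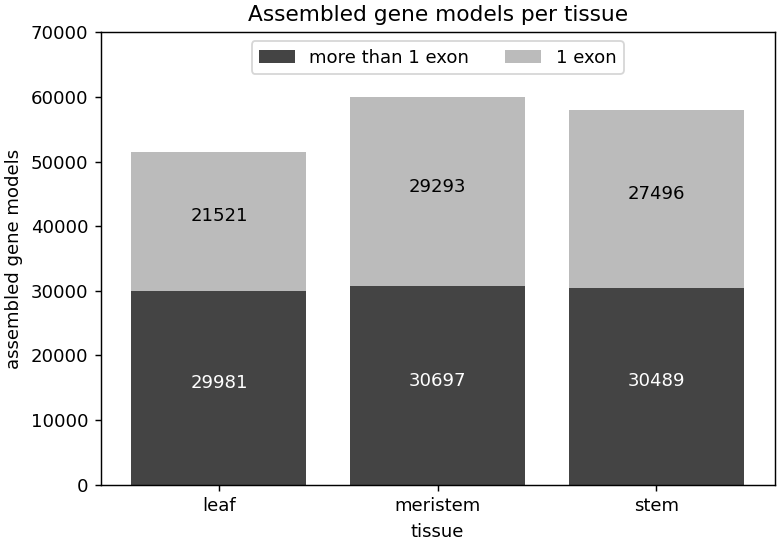
Number of assembled gene models (vertical axis) in the leaf, meristem and stem tables, divided into models with more than 1 exon (dark) and with 1 exon (light). Multi-exon models lie between 29981 and 30697 in each tissue, while single-exon models range from 21521 in leaf to 29293 in meristem.

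Joined by position, the models formed 67811 loci. Of these, 33811 (49.9%) had a model in all 3 tissues, and these loci took 99.7% of leaf fragments, 98.9% of meristem fragments and 99.1% of stem fragments. A model was present in leaf alone at 3237 loci, in meristem alone at 11012 and in stem alone at 8899. Loci of a single tissue were weakly expressed, with median levels of 0.147, 0.147 and 0.159 unscaled CPM in leaf, meristem and stem. They were mostly single-exon, at 84.6%, 84.9% and 85.4%. Only 2, 4 and 4 of them reached 10 unscaled CPM.

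At a level of 1 unscaled CPM, 25618 loci were detected in leaf, 30012 in meristem and 28839 in stem. All tissues shared 22144 of the 34420 loci detected anywhere (64.3%). Detection in a single tissue was seen at 875 loci for leaf, 2791 for meristem and 2849 for stem. The TMM factors, which raise leaf levels relative to the other tissues, were not applied here. The limit was therefore stricter for leaf.

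Leaf RNA was concentrated in few genes. The 10 most abundant gene models took 9.79% of leaf fragments, 3.38% of meristem fragments and 3.93% of stem fragments. The 100 most abundant took 26.9%, 12.6% and 13.8%. The most abundant leaf locus lay on contig 000046F at 635916 to 637000 (plus strand, 3 exons). It took 2.182% of leaf fragments (95% interval 2.18 to 2.184), 0.0926% in meristem and 0.0501% in stem, which is 36.3-fold and 64.7-fold higher in leaf after scaling. The most abundant meristem locus lay on contig 003132F at 312436 to 315749 (plus strand, 7 exons in meristem). It took 0.7894% of meristem fragments (0.7879 to 0.7909), 0.1613% in leaf and 0.01302% in stem, and was 58.5-fold higher than in stem and 3.18-fold higher than in leaf after scaling. The most abundant stem locus lay on contig 005160F at 160597 to 162779 (plus strand, 2 exons in stem). It took 1.056% of stem fragments (1.055 to 1.058), 3.52-fold more than in leaf and 6.26-fold more than in meristem after scaling. Its model was shorter in meristem, with 1170 bases and 1 exon, against 1775 bases in stem and 1920 in leaf. These 3 loci were chosen after their values were seen, and the meristem locus is overlapped by a model on the other strand.

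The tissue-enriched loci, at least 4-fold above both other tissues, numbered 1148 in leaf, 595 in meristem and 871 in stem, of 17864 loci compared across all tissues. The leaf-enriched loci took 33.8% of all counted fragments in leaf, and 4.68% in meristem and 3.58% in stem. The stem-enriched loci took 10.9% in stem, against 0.80% in leaf and 1.15% in meristem. The meristem-enriched loci took 5.99% in meristem, against 0.50% in leaf and 0.22% in stem. Median levels within the enriched tissue were 71.2 normalised CPM for leaf, 29.7 for meristem and 34.2 for stem. Multi-exon loci made up 79.9% of the leaf-enriched, 88.6% of the meristem-enriched and 79.0% of the stem-enriched loci, against 89.3% of all loci compared.

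The order of these counts depended on whether scaling factors were applied. The TMM factors raise leaf levels relative to the other tissues. Without the factors, 620 loci were leaf-enriched, 982 meristem-enriched and 1113 stem-enriched. The fragment shares kept their order under this alternative, since the 620 leaf-enriched loci took 27.3% of leaf fragments, the 1113 stem-enriched loci 14.4% of stem fragments and the 982 meristem-enriched loci 9.66% of meristem fragments.

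**Figure D2:**
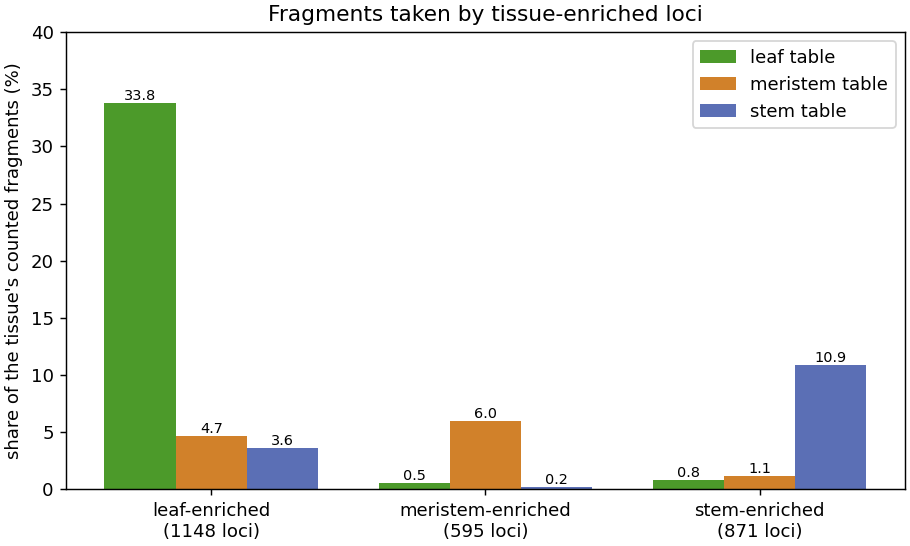
Share of each tissue's counted fragments in percent (vertical axis) taken by the leaf-enriched, meristem-enriched and stem-enriched loci, with 1 bar per tissue table and no error bars because each tissue has 1 count column. The leaf-enriched loci took 33.8% of leaf fragments, the largest share of the 9 bars.

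Leaf and meristem were the most alike pair by the number of loci called. Of 16201 loci compared, 1755 were at least 4-fold higher in leaf and 1030 at least 4-fold higher in meristem, together 17.2%, while 9254 (57.1%) differed by less than 2-fold. Differences above 100-fold were found at 18 loci in favour of leaf and at 35 in favour of meristem. The loci higher in leaf took 38.5% of leaf fragments and 5.8% of meristem fragments. Those higher in meristem took 7.6% of meristem fragments and 0.7% of leaf fragments. The loci higher in meristem were multi-exon in 90.5% of cases and those higher in leaf in 80.3%. Across all 36553 loci with a model in both tissues, the correlation of log2(CPM + 1) was 0.86 (Pearson) and 0.86 (Spearman), and loci are not independent replicates.

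The largest differences between leaf and meristem were at loci with few fragments in the lower tissue. A single-exon locus on contig 003470F at 22962 to 23748 (minus strand) had 15317 fragments in meristem (STRG.41336) and 5 in leaf (STRG.35374), a 2384-fold difference with a counting interval of 1021 to 7343. Its model covered 713 bases in meristem and 270 in leaf, and the difference per base was 903-fold. The next in that direction, on contig 002530F at 356972 to 360215 (plus strand), had 3869 fragments in meristem and 4 in leaf (753-fold, 294 to 2764), with models of 3244 and 256 bases. Per base of model it was 59.4-fold higher. Higher in leaf was a single-exon locus on contig 005802F at 239944 to 240320 (minus strand), with 1877 fragments in leaf and 4 in meristem (603-fold, 235 to 2215). Its models were of nearly equal length, 371 and 370 bases, and a model on the other strand overlaps it. Second was a locus on contig 002916F at 66705 to 68932 (plus strand), with 2250 fragments in leaf and 6 in meristem (482-fold, 221 to 1314). It was 165-fold higher per base of model.

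Which tissue of this pair held more high loci turned when the scaling factors were left out and with the CPM minimum. Without the factors 947 loci were higher in leaf and 2167 in meristem, so that the leaf share of the calls went from 63.0% to 30.4%. With a CPM minimum of 1, 3031 loci were higher in leaf and 3128 in meristem, a leaf share of 49.2%. The median log2 difference of the loci compared was 0.08 with the factors and -0.65 without them.

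Leaf and stem had the largest share of loci called at 4-fold and the lowest correlation. Of 16528 loci compared, 2977 were at least 4-fold higher in leaf and 1724 at least 4-fold higher in stem, together 28.4%, and 7106 differed by less than 2-fold. The loci higher in leaf took 46.2% of leaf fragments and 5.7% of stem fragments, and those higher in stem took 15.8% of stem fragments and 1.4% of leaf fragments. More than 100-fold differences were found at 162 loci in favour of leaf and at 86 in favour of stem. The correlation across 35438 loci was 0.77 (Pearson) and 0.77 (Spearman).

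By counts, the highest leaf over stem ratio among the loci compared was on contig 001519F at 59394 to 61858 (plus strand). It had 5584 fragments in leaf (STRG.22373) and 4 in stem, a 1597-fold difference (623 to 5863). Its models covered 2453 and 625 bases, the difference per base of model was 407-fold, and a model on the other strand overlaps it. A locus on contig 003040F at 186893 to 187950 (plus strand, 2 exons in leaf) had 4886 fragments in leaf and 4 in stem (1397-fold, 545 to 5130). Its models covered 697 and 501 bases, and per base the difference was 1004-fold, above that of the locus on 001519F. Higher in stem was a locus on contig 001375F at 343988 to 345529 (minus strand), with 3461 fragments in stem and 6 in leaf (504-fold, 231 to 1375). It too is overlapped by a model on the other strand, and its models were of 1495 and 309 bases, with a 104-fold difference per base. The locus on contig 002530F that was higher in meristem than in leaf was also higher in stem than in leaf, with 2054 fragments against 4 (449-fold, 175 to 1649). Its models covered 2670 bases in stem and 256 in leaf, and per base the log2 difference of leaf over stem was -5.43, against -8.81 from the counts. Without scaling factors 1962 loci were higher in leaf and 3049 in stem, so the leaf share of the calls went from 63.3% to 39.2%, and the median log2 difference from 0.08 to -0.65.

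Between stem and meristem, 1577 loci were at least 4-fold higher in stem and 2112 at least 4-fold higher in meristem, of 16370 compared (22.5% together). Loci within 2-fold numbered 8389 (51.2%). The loci higher in stem took 19.3% of stem fragments and 2.7% of meristem fragments. Those higher in meristem took 19.8% of meristem fragments and 1.5% of stem fragments. Differences above 100-fold favoured meristem at 244 loci and stem at 45. Scaling mattered little here, since without the factors the counts were 1595 and 2358. The correlation across 40294 loci was 0.81 (Pearson) and 0.81 (Spearman).

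A locus on contig 000988F at 664 to 2405 (plus strand) had 2735 fragments in meristem and 1 in stem. The ratio of 2435 has a counting interval of 437 to 96200, which contains that of the next locus, so the order of these loci is not fixed. The models covered 1254 and 203 bases, and the ratio per base was 394. A 13-exon locus on contig 004180F at 256695 to 261420 (plus strand) had 6763 fragments in meristem and 4 in stem (1505-fold, 588 to 5526). Its stem model covered 209 bases against 3478 in meristem, and per base of model the difference was 90.5-fold. Higher in stem was a 3-exon locus on contig 000241F at 882235 to 883979 (plus strand), with 7603 fragments in stem and 6 in meristem (1423-fold, 654 to 3880). Its models covered 1581 and 470 bases, and the difference per base was 423-fold. A 3-exon locus on contig 000063F at 1907106 to 1920819 (plus strand) had 1658 fragments in stem and 3 in meristem, a ratio of 621 with a counting interval of 212 to 3013. With models of 668 and 225 bases, the ratio per base was 209.

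**Figure D3:**
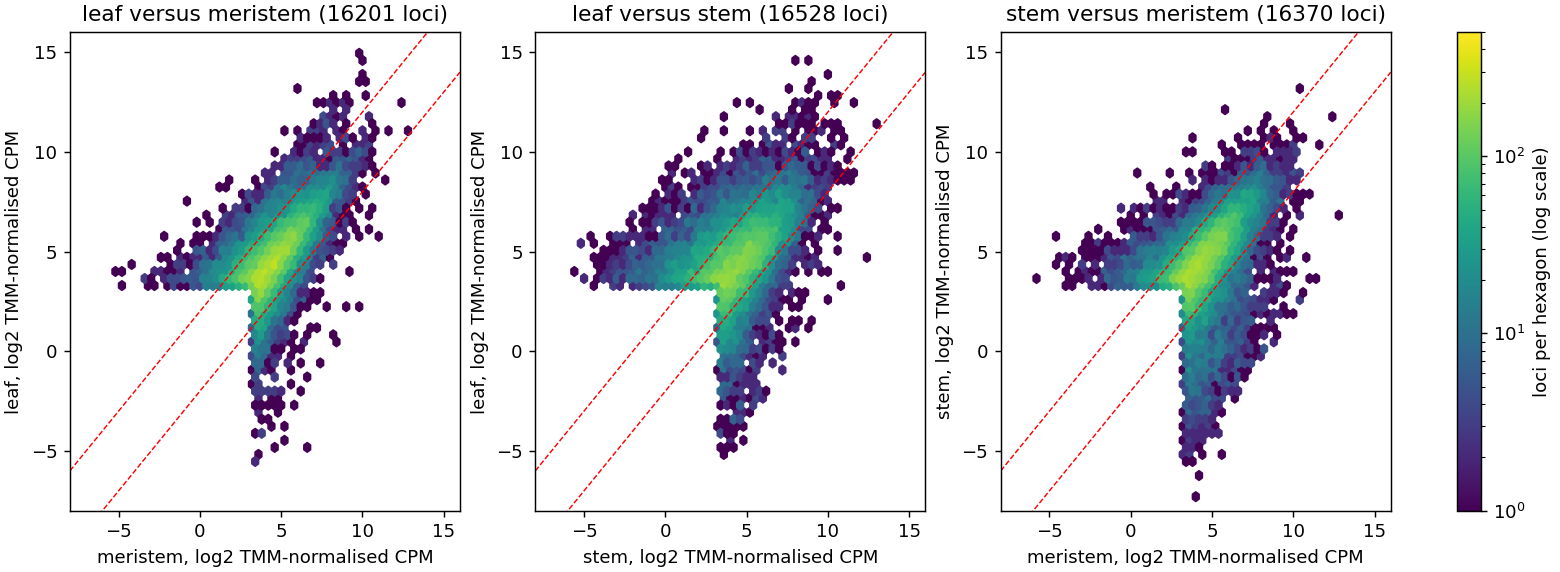
Log2 TMM-normalised CPM of each locus compared in 1 tissue (vertical axis) against another (horizontal axis), for leaf versus meristem (16201 loci), leaf versus stem (16528) and stem versus meristem (16370). Colour gives the number of loci per hexagon on a log scale and dashed lines mark 4-fold differences, outside which 17.2%, 28.4% and 22.5% of the loci lie.

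Models were more often cut short where a locus was low. The model in the lower tissue was at most 50% as long as that in the higher tissue at 9.4%, 9.6% and 11.0% of the called loci for leaf versus meristem, leaf versus stem and stem versus meristem. Among loci not called the shares were 1.2%, 1.2% and 0.9%. Of the 11175 calls in the 3 comparisons, 9884 (88.4%) kept a fold of at least 4 in the same direction when counts were divided by model length, and 19 changed direction. With 1 count column per tissue, none of these differences could be set against the spread between samples.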

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

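No paired analysis was possible because the count columns carry no replicate number. For the same reason the quasi-likelihood and DESeq2 tests, the fold-threshold test and the removal of single libraries were not run. The gene list tests were not run because the gene numbers are not paired with gene names. Organelle sequences could not be identified by name either. The 6 counts of loci per direction and the 3 tissue-enriched counts stayed within 1.5 times under RLE size factors, with no filter, with merging by span and without loci overlapped on the other strand (the last 2 chosen after seeing the data). Scaling within each pair, run for the 6 counts, kept them within 1.5 times too. The filter removes only loci far below the CPM minimum, so it can act only through the factors. The 11 named loci, 1 of them named in both comparisons with leaf, kept their direction under each alternative that gave them a value. In the lists that follow, values are ordered as leaf and meristem in leaf versus meristem, leaf and stem in leaf versus stem, stem and meristem in stem versus meristem, then leaf-, meristem- and stem-enriched. With a CPM minimum of 1 they were 3031, 3128, 4953, 3987, 3343 and 4087, with 1058 meristem-enriched and 1507 stem-enriched loci. With a fold of 2 they were 4025, 2922, 5231, 4191, 3870, 4111, 2728, 1545 and 2510. With 1 model per tissue and a length offset (19176 loci) they were 922, 327, 1609, 791, 779, 1012, 632, 188 and 423, where fewer loci enter by construction. On the same loci without the offset, 261 were higher in meristem than leaf, 1892 in leaf and 734 in stem for leaf versus stem, 875 and 953 for stem and meristem, and 154 and 418 were meristem- and stem-enriched. On the 9714 loci with model lengths within 10% they were 683, 139, 1088, 345, 465, 546, 420, 92 and 188. The leaf share of the leaf versus meristem calls was then 83.1%, against 63.0% over all loci, and the share for leaf versus stem 75.9% against 63.3%. With 1 model per tissue and the offset the leaf share was 73.8% against meristem, and with counts per base of model 73.4%, where 642 loci were higher in meristem than leaf. At a CPM minimum of 1 it was 49.2%. Without scaling factors 947 and 2167 loci were higher in leaf and meristem, 1962 and 3049 in leaf and stem, and 620 and 982 were leaf- and meristem-enriched. With RLE factors the leaf share was 64.5% against meristem and 63.6% against stem, and with scaling within each pair 64.9% and 63.4%. Whether leaf or the other tissue holds more high loci therefore depends on whether scaling factors are applied. For leaf versus meristem it also depends on the CPM minimum. In the order of the comparisons, 0 calls rested on a count of 0 and 3, 1 and 5 calls on 1 to 3 counts in the lower tissue. A model needs reads, so loci near 0 in the lower tissue were mostly not compared, and these counts do not measure the effect of depth. Loci at 10 normalised CPM or more without a model in the other tissue were left out of the calls. They numbered 6 in leaf and 12 in meristem for leaf versus meristem, and 32 in leaf and 32 in stem for leaf versus stem. For stem versus meristem they numbered 11 in stem and 43 in meristem.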

Other observations

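Of the tests in this part, the 2 on the density of loci missing in leaf, the intron test on loci missing in leaf, the exon-number test and the strand test on multi-exon loci were set out before their values were seen, and the others after, as was the comparison of exon numbers with random pairs of enriched loci. Loci that were low in one tissue only were most numerous in stem. At 1104 loci the stem level was at least 4-fold below both other tissues, against 208 for leaf and 220 for meristem. Without scaling factors these counts were 900, 587 and 124. The loci low in stem took 14.4% of meristem fragments and 11.1% of leaf fragments but 0.92% of stem fragments, with median levels of 45.3, 41.6 and 3.0 normalised CPM. At the other end, 4835 loci (27.1% of those compared) lay within 2-fold in all tissues. They took 18.5% of leaf fragments, 27.9% of meristem fragments and 27.7% of stem fragments, and 94.1% were multi-exon.

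Loci enriched in the same tissue lay next to each other on the contigs more often than random lists of the same size matched on level. Among 13009 adjacent pairs of compared loci, 228 were enriched in the same tissue, against a mean of 100.8 and a highest value of 137 in 10000 random lists. The excess held for each tissue, with 102 pairs against 55.6 for leaf, 45 against 14.4 for meristem and 81 against 30.8 for stem. One run of 4 meristem-enriched loci lay on contig 006872F between 144426 and 151293, all on the minus strand. Another run of 4, stem-enriched, lay on contig 003685F between 205764 and 234425 on both strands. These runs were chosen after their values were seen.

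The excess lay mainly on 1 strand and at close range. Pairs on 1 strand numbered 95 against 15.0 at random within 5 kb and 69 against 38.4 over 5 kb apart, together 164 against 53.4. On opposite strands there were 64 against 47.4, reached by 123 of the 10000 lists, and within 5 kb 22 against 13.5, reached by 199. Among multi-exon loci on opposite strands, whose strand follows from splice sites, there were 44 against 39.2, which 2383 lists reached. The pairs on opposite strands with at least 1 single-exon locus, whose strand is less sure, numbered 20 against 8.2, reached by 5 lists. The random lists were matched on level and not on exon number. Multi-exon loci made up 79.9% of the leaf-enriched, 88.6% of the meristem-enriched and 79.0% of the stem-enriched loci, against 89.3% of all loci compared. The random mean may therefore be too high for multi-exon pairs and too low for pairs with a single-exon locus. For the pairs with a single-exon locus and for the pairs on 1 strand, broken genes and neighbouring copies cannot be told apart, because no sequence was compared. Of the 69 pairs on 1 strand over 5 kb apart, 23.2% (13.9 to 34.9) had equal exon numbers. The share was 9.5% among other adjacent pairs and 11.2% among random pairs of enriched loci. Tandem or duplicated copies may contribute to this. Pairs of loci with 1 exon each count as equal too and were not separated, so the share does not tell copies from broken genes. Only 1.87% of introns in the models exceed 5 kb. An intron at which a gene was broken is not in the models, so this share does not exclude broken genes. Shared regulation of neighbouring genes was not tested.

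The smaller number of gene models in leaf was almost wholly a difference in single-exon models, which made up 91.6% of the gap to meristem and 92.2% of the gap to stem. Leaf did not have fewer counted fragments, since its total was 1.20 times the higher of the other totals. The number of aligned reads from which the models were assembled was not examined. At loci with a model in all tissues, leaf had 1.08 times as many models per locus as the higher of the others. Breakage at these loci therefore does not make the gap. A broken piece that shares no exonic base with a model of another tissue forms a locus of its own, which this ratio leaves out. Loci of a single tissue numbered 11012 in meristem and 8899 in stem, against 3237 in leaf. Whether they hold such pieces was not tested, so broken models stay open there. Unspliced RNA inside introns may account for part of the gap. Single-exon models inside a multi-exon locus on either strand made up 19.0% of the net single-exon gap to meristem and 18.3% of that to stem. Models in a locus that also held a multi-exon model were not counted as inside. Introns of genes without a spanning multi-exon locus could not be seen. Intronic pieces counted in this way therefore do not make most of the gap, while pieces of those other kinds stay open. Of the single-exon loci missing in leaf 8.2% lie inside a multi-exon locus on the same strand, against 1.2% of those in all tissues. Lower effective depth of leaf after scaling stays open. Of the 6483 loci modelled in meristem and stem but not leaf 32.7%, and of the 19911 modelled in only one of them 45.5%, would fall under the 10th percentile of leaf count density. Both shares lay under 50% by more than their binomial intervals over loci (31.6 to 33.9 and 44.8 to 46.2), which treat loci as independent. By the rule set beforehand this went against effective depth. That bound of 50% was judged wrong afterwards, because it concerns all loci missing in leaf. The pattern is a net gap of 8488 models to meristem and 6483 to stem, and the test on that gap was set afterwards. Among models at or above the 10th percentile of leaf the gap was 5108 to meristem and 2899 to stem. Scaling their densities to the effective depth of leaf left 2062 (40.4%) and 1461 (50.4%). For meristem the gap went from 1440 to -2043 at the 25th percentile and from 1564 to -1251 at the 50th. For stem there was no gap to remove at these percentiles, with -525 and -288 models before scaling. Scaling down can only lower the numbers of meristem and stem, so a smaller gap alone does not argue for effective depth. The negative values for meristem went past an equal number, which the rule did not foresee. The test asked for the same outcome in both tissues and so does not decide. A wider range of weak transcripts in meristem and stem, genomic DNA and differing library quality stay open and untested.

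Shorter models in the lower tissue may account for part of the calls and of the size of the biggest folds, but not for most calls. After division by model length 88.4% of all calls kept a fold of at least 4, while the loci higher in meristem than in leaf went from 1030 to 642. Of the 590 differences above 100-fold, 377 stayed above 100-fold. These were 28 of 53 for leaf versus meristem, 169 of 248 for leaf versus stem and 180 of 289 for stem versus meristem. In 107 of the 590 the lower tissue had at most 10 fragments, so the size of those folds is poorly fixed by counting alone. Tissue differences in transcript level are the biological explanation, not testable against sample variation with 1 column per tissue. The protocols speak of 1 library per tissue on a lane of its own, so effects of library and lane cannot be told apart from tissue.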
